A study of Mus musculus and Rattus norvegicus with 18 samples.

How the data were processed

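The series holds 18 samples: 4 heart RNA-seq, 4 heart Ribo-seq and 4 heart tRNA libraries from Ctrl and cKO mice, and 6 H9C2 RNA-seq libraries. Groups and replicate numbers were taken from the sample labels, and table columns were matched to samples by name. The authors deposited a table of read counts per gene for heart RNA-seq, a table of footprint counts per open reading frame for Ribo-seq and a table of read counts per gene for H9C2, all as whole numbers with no normalization. These units were read from the values, since the labels do not state them. The submitters' processing notes name GRCm38, Rnor_6.0, cutadapt, STAR, HISAT2, featureCounts, StringTie, DESeq2, Bowtie and Bowtie2, and which tool made which table, with which version, strand setting or annotation, is not given in the sources used here. The H9C2 columns are named after annotation files, so those counts may have been derived from the transcript coverage that StringTie writes, which is left open here. Ribo-seq libraries were prepared with a small RNA kit per the labels. Nothing in the sources used here says how reads that match several places were counted, so genes with near-identical copies are reported as uncertain.

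The heart RNA table lists 55487 gene IDs, 55141 of which have a symbol in the mouse name table used here. The rat table lists 32883 IDs, 396 without a symbol. Mouse coordinates are those of GRCm38.p6 gene records, and no rat coordinates are given. The Ribo-seq table lists 26398 frames of 17866 genes, and 5613 genes have more than 1 frame. The frame with the most footprints over the 4 libraries was kept for each gene, and these frames hold 98.914% of all footprints. This choice was made on seeing the table. For 751 genes the kept frame is not the longest one.

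Each comparison of genes used edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Heart RNA and Ribo were fitted apart (2 against 2), and H9C2 was fitted with 3 against 3. Translational efficiency was tested as the interaction of genotype and assay in 1 model over the 8 heart libraries, for genes that passed the filter in both assays. The SE of a log2 fold change was the absolute value divided by the square root of the F statistic. Levels are CPM with TMM factors, as mean ± SD over libraries. Ratios of genes with 1 to 3 counts in a group carry an exact 95% interval, and a fold against a group at 0 was computed against 3 counts over the group.

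Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, for lists with at least 5 tested genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The 44 lists, with 990 entries, cover fuel metabolism, mitochondria, the translation machinery, stress responses, heart and muscle programmes, and markers of other cell types. Alternatives were camera with an estimated correlation and fry. Designs, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Mettl1 and Wdr4, 5 ketone body genes in the heart, the 8 largest changes per direction among genes past adjusted p 0.05 with a mean of at least 1 CPM and no overlap between the groups' libraries (predicted gene models left out), and 2 to 4 genes of each list with the smallest adjusted p. A few genes picked by the rule are not reported here. Other list genes with their values, such as those that moved against their list, and genes shared between heart and H9C2 were chosen after their values were seen.

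Counts of changed genes and the named genes were recomputed with relative-log-expression factors, with library totals (for translational efficiency, factors within each assay), with DESeq2 1.42.0, with limma-voom (not for translational efficiency), with at least 1 count as the sole filter, with at least 50 counts in every library of a group, with the replicate number as a block and without each replicate in turn, and the counts also with a further 2-fold threshold. For translational efficiency a replicate left out is the RNA and the footprint library of 1 number, and libraries were matched by number to find genes with no overlap. The block there joined the RNA and the footprint library of 1 genotype and number. In the other comparisons it joined libraries of 1 number across genotypes. The labels do not tie RNA and footprint libraries of 1 number to 1 heart, and the main interaction test does not match them. Lists were recomputed with relative-log-expression factors, the block and without each replicate, beside camera with an estimated correlation and fry, and only their medians with library totals. Correlations of fold changes were recomputed with at least 50 counts and, added after the data were seen, without each library. Footprints summed over all frames and the longest frame were also added after the data were seen. Library totals moved the median log2 fold change of all genes to 0.080 in heart RNA, 0.073 in Ribo and 0.042 in H9C2.

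The tests were tried on simulated negative binomial counts with 200 genes changed 2-fold. Means and library sizes were those of the real data, and dispersions followed the fitted trend rather than each gene. They recovered 81.5% in heart RNA (13866 genes), 75.0% in Ribo (13325), 74.5% in translational efficiency (12499) and 82.0% in H9C2 (14571), with 1.81%, 0%, 1.33% and 4.09% of calls false. A shifted list was called in each, and 0 of 100 unshifted lists were. Simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely. Counts of every pair of replicates differed by more than sampling noise (chi-square over genes with at least 20 counts), so no replicate is a copy of another. The labels give no batch or date.

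The tRNA table was not used: it has 2 columns, 1 per genotype, while the labels describe 2 tRNA libraries per genotype, and neither column could be tied to 1 of them. The planned tRNA comparisons were therefore not run, and a planned relation of translational efficiency to codon content was not run because coding sequences were not used here.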

Results

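The series asked what loss of Mettl1 does to the heart. Mettl1 is the catalytic subunit of the enzyme that adds N7-methylguanosine to a set of tRNAs, and Wdr4 is its partner subunit. The series title names ketogenesis, translational regulation and maturation of cardiomyocytes. Whole hearts of 4-week-old C57BL/6 mice with a conditional knockout (cKO) and of controls (Ctrl) were measured by RNA-seq and by Ribo-seq, which sequences the RNA stretches covered by ribosomes. Each genotype had 2 libraries per assay. H9C2, a myoblast line from embryonic rat heart, was measured by RNA-seq in 3 unedited samples (WT) and 3 samples of a Mettl1-null line with a CRISPR frameshift. A further 4 tRNA libraries, which complete the 18 samples, were not analysed here. Library totals ranged from 15.05 to 16.84 M counts in heart RNA-seq, from 25.17 to 39.68 M footprints in Ribo-seq and from 90.32 to 94.2 M counts in H9C2. Nothing in the labels says that replicates were separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

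Mettl1 (ENSMUSG00000006732, GRCm38 chromosome 10, 127041549 to 127046365) was lower in every library without it. In heart RNA it stood at 4.31 and 3.76 CPM (counts scaled to a common library size) in the Ctrl libraries and at 2.49 and 2.52 in the cKO libraries. Its log2 fold change was −0.69 (SE 0.24, n = 2 against 2), and its adjusted p of 0.0664 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment did not pass 0.05. It passed with no count filter (adjusted p = 0.0408) and with a stricter one (0.0437). Footprints on Mettl1 fell from 6.28 and 6.62 CPM to 2.22 and 2.22, a log2 fold change of −1.54 (SE 0.21, adjusted p = 1.0e-04). In H9C2, Mettl1 fell from 16.2 ± 0.503 to 4.25 ± 0.488 CPM (SD, n = 3 each), or −1.93 (SE 0.11, adjusted p = 1.1e-05). The labels do not give the deleted exon or the cells in which it was deleted, so RNA left in cKO hearts can come from cells outside the deletion or from the rest of the transcript, and Eef1akmt3 overlaps the gene. Wdr4 had log2 fold changes of 0.23 in heart RNA (adjusted p = 0.383), 0.41 in footprints (0.208) and −0.02 in H9C2 (0.897). The H9C2 value of Wdr4 turned to 0.02 with library totals and to between 0.01 and 0.03 without WT 1, WT 2 or null 1.

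**Figure D1:**
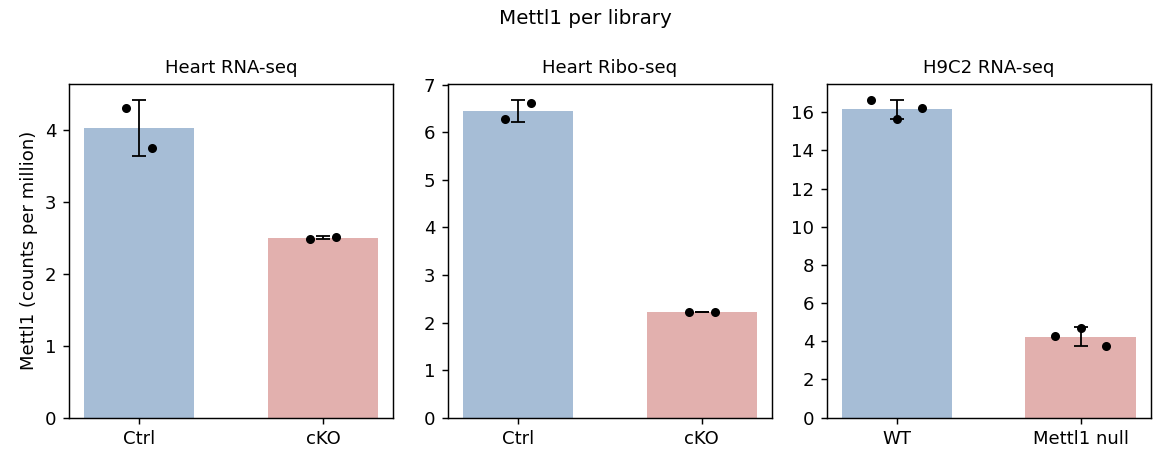
Mettl1 in CPM (y axis, TMM-scaled) per library in heart RNA-seq, heart Ribo-seq and H9C2 RNA-seq. Points are libraries, bars are group means and whiskers are 1 SD (n = 2, 2 and 3 per group), and every cKO or null library lies below every Ctrl or WT library.

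In cKO heart RNA 4 genes linked to cardiac stress or the fetal heart, Nppa, Nppb, Ankrd1 and Acta1, rose, and Ppargc1a and Idh3a, of mitochondrial fuel use, fell. Nppa and Nppb, which encode natriuretic peptides, rose by 3.597 (SE 0.11) and 2.62 (SE 0.08) on the log2 scale, Nppa from 66.4 ± 6.49 to 803 ± 164 CPM and Nppb from 51.3 ± 6.24 to 316 ± 3.85 (SD, n = 2 each). Ankrd1, a stress-responsive sarcomere protein, rose from 298 ± 49.7 to 1810 ± 121 CPM, and Acta1, the skeletal actin also made by the fetal heart, from 188 ± 33.3 to 1292 ± 143. Ppargc1a, a coactivator of mitochondrial gene expression, fell from 173 ± 19.1 to 88.1 ± 0.389 CPM (−0.97, SE 0.07), and Idh3a of the citric acid cycle fell from 614 ± 11.03 to 417 ± 7.79 (−0.56, SE 0.05). Adjusted p-values of these 6 genes ranged from 2.0e-11 to 3.5e-06 in edgeR's test. Of 14088 genes tested, 1150 rose and 882 fell, of which 265 and 27 changed at least 2-fold. The libraries of the genotypes did not overlap for 55.0% of all tested genes, against 33.3% by chance. With library totals in place of TMM factors the split was 1769 up and 506 down.

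Gdf15 and Tbx15 headed the genes that rose. Gdf15, a secreted stress cytokine, rose from 0.671 ± 0.312 to 21.9 ± 1.33 CPM (5.01, SE 0.22; chromosome 8, 70629393 to 70632470). Tbx15, a T-box transcription factor, rose from 0.416 ± 0.0485 to 15.4 ± 2.07 CPM (5.19, SE 0.26; chromosome 3, 99240348 to 99354260). Their adjusted p-values were 1.1e-09 and 3.0e-09. The metallothionein gene Mt3 rose by 4.65, the water channel gene Aqp8 by 4.57, Plcxd2 by 4.02 and Tceal7 by 3.87. Tnfsf18 rose by 4.18, by 3.40 without Ctrl 1 and by 6.04 without Ctrl 2. Gsta1 had 3 counts in Ctrl against 80 in cKO, a ratio of 26.9 (95% counting interval 8.88 to 133), and it has the close copy Gsta2. Its log2 fold change of 4.57 was 3.61 without Ctrl 2, and without Ctrl 1 the remaining Ctrl library had 0 counts. The interval covers counting error only. Fosb, an immediate early gene, fell from 9.09 ± 0.382 to 3.28 ± 1.21 CPM (−1.48, adjusted p = 2.2e-04). The muscle chloride channel gene Clcn1 fell by 1.39 and Dbh, which makes noradrenaline, by 1.38 (adjusted p = 0.00222 and 0.00141). Lrat, a vitamin A esterifying enzyme, fell by 1.60 (adjusted p = 0.01001) but had 0.159 without Ctrl 1 and 0.0796 without cKO 1. Epop (−1.40) passed in edgeR and not in DESeq2 (adjusted p = 0.128), and was also lost without Ctrl 2 (0.0927) or cKO 1 (0.185). Cenpp (−1.58) was lost in DESeq2 (0.137) and without Ctrl 2 (0.170), cKO 1 (0.142) or cKO 2 (0.0837). Cenpp, Uckl1os (−1.41), Clcn1 and Lrat are uncertain because each overlaps other genes (Fam131b for Clcn1, Rbm46os for Lrat) and the counting strand is not given in the sources used here, and predicted genes overlap Tbx15 and Plcxd2.

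Lists of genes fixed before the data were examined were compared with all other genes by camera at a preset correlation of 0.01. In heart RNA 18 of 39 lists passed an adjusted p of 0.05, 0 with a correlation estimated from the data (11 at an unadjusted p under 0.05) and 15 by fry, which asks whether a list moves one way. Across the comparisons only 2 camera calls held with an estimated correlation, both in H9C2. In heart RNA, lists with an estimate under the preset 0.01 lost their call too, such as fetal cardiomyocyte genes (−0.019) and p53 targets (−0.048). A lost call is thus by itself no sign that genes of a list move together. Heart RNA and Ribo had 2 against 2 samples and H9C2 3 against 3, so this setting does not contrast heart with H9C2.

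Of 22 fetal cardiomyocyte genes, 11 rose and 3 fell in heart RNA, the same numbers when adjusted over the list alone (median 0.30, camera adjusted p = 8.7e-29, adjusted p = 0.128 with an estimated correlation). Myh7, the slow myosin heavy chain, rose from 87.1 ± 14.6 to 245 ± 16.5 CPM (1.49, SE 0.09), and the channel genes Hcn4 (−0.99) and Cacna1g (−0.65) were among those that fell. Of 15 skeletal myogenic genes 8 rose and 1 fell, 8 and 1 adjusted over the list alone, among them Tnnc1 (0.60) and Tnnt1 (0.89) of the troponin complex (camera 1.7e-08, adjusted p = 0.165 with an estimated correlation). Among 10 atrial markers Nppa, Clu and Bmp10 rose and Stard10 fell, 3 and 1 adjusted over the list alone (camera 2.3e-04, adjusted p = 0.578 with an estimated correlation; without Ctrl 1 the camera value was 0.318). Of 32 adult cardiomyocyte genes 17 fell and 0 rose, 19 and 1 adjusted over the list alone (median −0.17, camera 9.7e-08, adjusted p = 0.131 with an estimated correlation). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 13430 ± 111 to 10430 ± 204 CPM, and Ryr2, its calcium release channel, from 1482 ± 5.98 to 1173 ± 19.95. Of 10 markers of cardiomyocytes as such 6 fell, 6 down and 1 up adjusted over the list alone, including Myh6 (−0.16) and Ttn (−0.38). That list passed camera at 0.00395 (adjusted p = 0.244 with an estimated correlation).

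Lists of mitochondrial fuel genes passed camera downward in heart RNA at its preset correlation, though not with an estimated one, and glycolysis genes did not pass. Of 26 genes of the citric acid cycle and pyruvate dehydrogenase, 19 fell and 1, the pyruvate carrier subunit Mpc1 (0.30), rose (20 and 1 adjusted over the list alone; median −0.25, camera 3.0e-12, adjusted p = 0.128 with an estimated correlation). Mdh1 fell from 1769 ± 28.3 to 1301 ± 53.9 CPM and Sucla2 from 386 ± 10.5 to 268 ± 26.5. Of 30 genes of fatty acid uptake and oxidation 17 fell and 1 rose, 21 and 1 adjusted over the list alone (median −0.20, camera 1.7e-08, adjusted p = 0.131 with an estimated correlation), with the fatty acid transporter Slc27a1 at −0.59 and the lipase Lpl at −0.40. Of 19 genes of amino acid and branched-chain catabolism 11 fell and 0 rose, 13 and 0 adjusted over the list alone (median −0.39, camera 2.2e-12, adjusted p = 0.128 with an estimated correlation), with Ivd at −0.56 and Pccb at −0.61. Of 13 mitochondrially encoded mRNAs 9 fell and 0 rose, 12 and 0 adjusted over the list alone (camera 1.2e-05, adjusted p = 0.165 with an estimated correlation), with mt-Nd5 at −0.36 and mt-Co1 at −0.24. All features with a mitochondrial gene symbol, a set not limited to these mRNAs, took 26.0% ± 0.446 of Ctrl counts and 23.2% ± 0.402 of cKO counts. Of 21 glycolysis genes 5 fell and 1 rose, 6 and 1 adjusted over the list alone (camera 0.158), and their median of −0.01 became 0.07 with library totals. The 50 nuclear genes of the respiratory chain did not pass (median 0.03, mean −0.00, camera direction down, adjusted p = 0.710), nor did the 59 mitochondrial ribosomal proteins (adjusted p = 0.585), whose median of −0.01 changed sign with library totals.

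Several lists of stress and translation genes passed camera upward in heart RNA at its preset correlation, though not with an estimated one, and others did not pass. Of 34 translation factors 6 rose and 4 fell, 6 and 4 adjusted over the list alone (median 0.05, camera 0.648). Of 21 ER chaperones 1 rose and 1 fell, 0 and 0 adjusted over the list alone (camera 0.668), and of 15 mitochondrial chaperones 4 fell and 0 rose, 4 and 0 adjusted over the list alone (camera 0.0530); the medians of both (−0.01 and −0.05) became positive with library totals (0.07 and 0.03). Of 21 p53 targets 10 rose and 0 fell, 11 and 0 adjusted over the list alone (camera 7.1e-15, adjusted p = 0.128 with an estimated correlation), among them Cdkn1a, a cell cycle inhibitor, from 158 ± 15.3 to 330 ± 25.8 CPM, Phlda3 (2.05) and Eda2r (2.12). Of 18 heat shock genes 10 rose and 0 fell, 11 and 0 adjusted over the list alone, led by the small chaperones Hspb1 (1.498) and Hspb8 (1.03), and camera gave 6.5e-12 (adjusted p = 0.128 with an estimated correlation). In the integrated stress response list of 31 genes 9 rose and 4 fell, 11 and 4 adjusted over the list alone (camera 1.1e-04, adjusted p = 0.165 with an estimated correlation): the amino acid transporter gene Slc7a5 rose by 1.20 and the transcription factor gene Ddit3 by 1.16, while the transporter gene Slc7a1 fell by 0.69. Of 20 cytosolic aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 9 rose and 1 (Eprs, −0.34) fell, 9 and 1 adjusted over the list alone, with Aars at 0.66 and Lars at 0.59 (camera 1.3e-04, adjusted p = 0.244 with an estimated correlation). Of 77 cytosolic ribosomal protein genes 39 rose and 0 fell, 54 and 0 adjusted over the list alone (median 0.26, camera 5.5e-13, adjusted p = 0.593 with an estimated correlation). Their mean level differed by 0.25, by 0.14 without cKO 1 (camera 1.1e-05) and by 0.36 without cKO 2 (1.6e-31). Rpsa stood at 0.37 and Rpl12 at 0.40, and these genes have many near-identical pseudogenes, so their counts are uncertain. Of 21 NRF2 antioxidant genes 6 rose and 0 fell, 8 and 0 adjusted over the list alone, with Srxn1 at 1.03 and Txnrd1 at 0.64 (camera 6.4e-05, adjusted p = 0.165 with an estimated correlation). Gsta2 of that list had 0 counts in Ctrl and 39 in cKO, at least 13.1-fold higher against 3 counts over the group. With Gsta2 at that bound the list's mean went from 0.737 to 0.568. Its median of 0.14 could not move, since Gsta2 lies above it either way.

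Markers of other cell types moved in both directions. Of 11 endothelial markers 3 fell, 5 adjusted over the list alone: Cldn5 (−0.49), Pecam1 (−0.21) and Fabp4 (−0.27), with camera at 0.0117 (adjusted p = 0.276 with an estimated correlation). Of 8 erythroid markers Alas2, Hba-a1 and Hbb-bs rose, 7 adjusted over the list alone (median 0.49, camera 0.0130, 0.532 without cKO 1, adjusted p = 0.684 with an estimated correlation), and haemoglobin took 0.144% ± 0.009 of Ctrl and 0.203% ± 0.063 of cKO counts. Of 40 matrix genes 9 rose, 9 adjusted over the list alone, with Ccn2 from 120 ± 5.37 to 359 ± 13.4 CPM and Tgfb2 at 1.11 (camera 4.8e-05, 0.0513 without Ctrl 1, adjusted p = 0.505 with an estimated correlation). Macrophage markers (median 0.13, camera 0.252), fibroblast markers (0.08, 0.583) and pericyte markers (−0.14, 0.0528) did not pass.

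**Figure D2:**
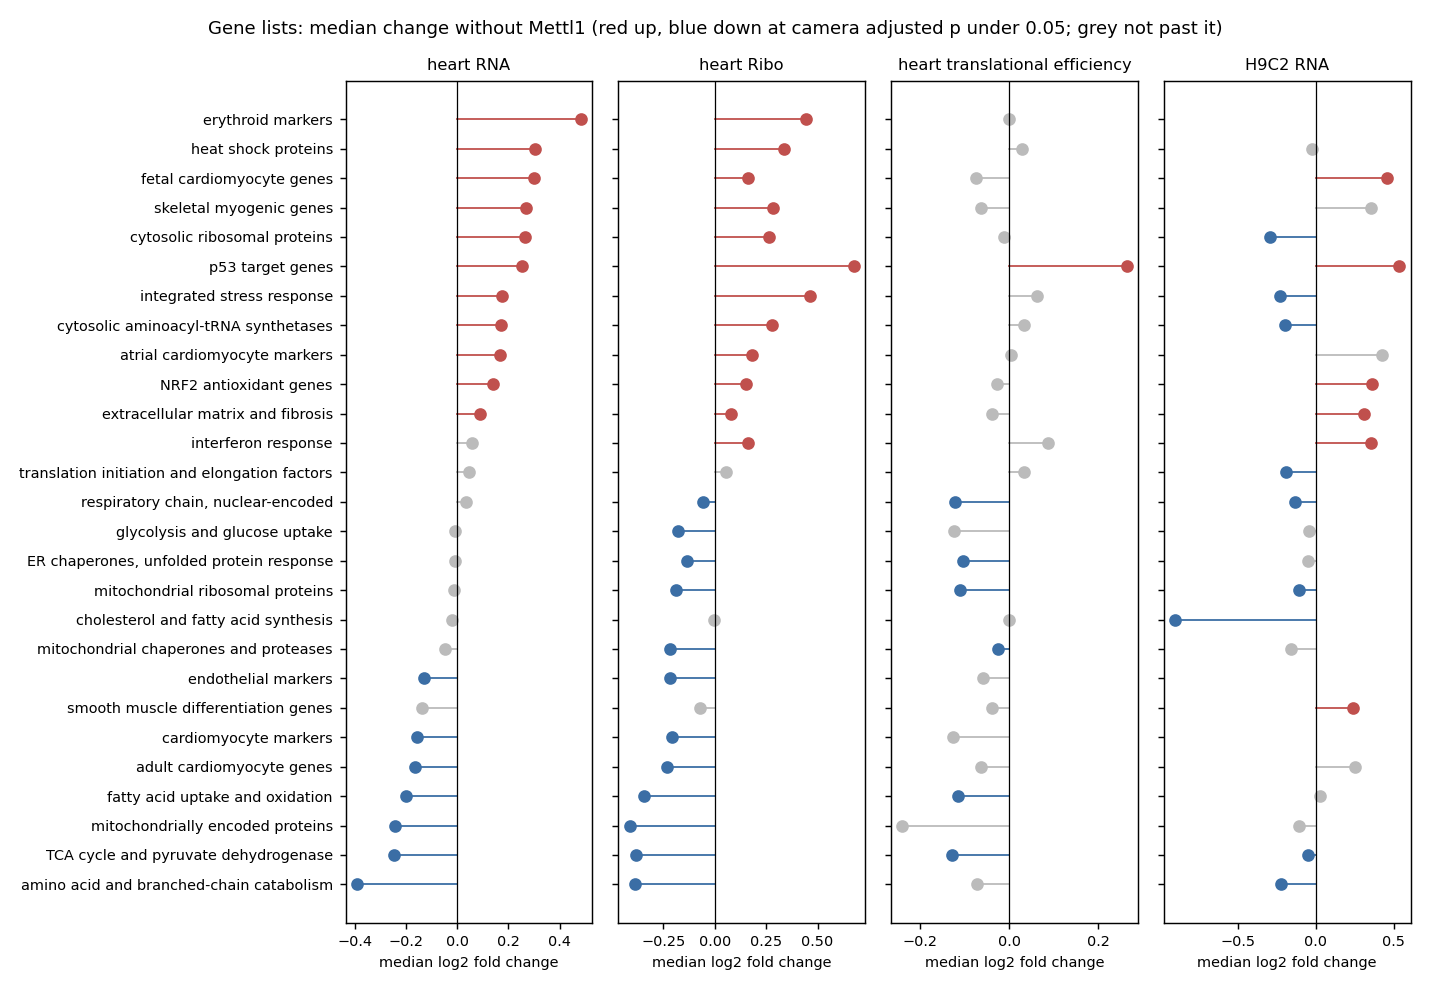
Median log2 fold change (x axis, a separate scale per panel) of gene lists tested in heart RNA that passed camera in at least 1 comparison, cKO over Ctrl in the heart (2 against 2) and Mettl1-null over WT in H9C2 (3 against 3); red and blue points passed an adjusted p of 0.05 at the preset correlation, upward and downward, and grey points did not. In other scaling (library totals, or factors per assay for translational efficiency) the sign turns for glycolysis, ER chaperones, mitochondrial ribosomal proteins, mitochondrial chaperones and cholesterol synthesis in heart RNA, respiratory chain and cholesterol synthesis in Ribo, ribosomal proteins and cholesterol synthesis in translational efficiency and heat shock proteins in H9C2, and only cholesterol synthesis and p53 targets in H9C2 held with an estimated correlation.

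Ketone body genes, which the series title points to, did not move as a group. Oxct1, the enzyme that activates ketone bodies for oxidation (chromosome 15, 4026428 to 4155344), fell from 920 ± 12.03 to 719 ± 0.157 CPM in RNA (−0.36, SE 0.05, adjusted p = 1.3e-04). Its footprints fell from 1162 ± 10.7 to 909 ± 50.5 CPM (−0.35, SE 0.08, adjusted p = 0.00467, but 0.0896 without cKO 2). Footprints on Acat1, the mitochondrial thiolase (chromosome 9, 53580522 to 53610350), fell by 0.28 (SE 0.08, adjusted p = 0.0186), a call lost with library totals (0.0710) and without Ctrl 1, cKO 1 or cKO 2 (0.0585, 0.126 and 0.14). Its RNA value was −0.13 (adjusted p = 0.120, and 0.0443 with the replicate number as a block). Footprints on Bdh1, the hydroxybutyrate dehydrogenase (chromosome 16, 31422297 to 31458901), rose by 0.53 (SE 0.12, adjusted p = 0.00818, and 0.160 without cKO 1), and its RNA value was 0.40 (adjusted p = 0.0849, and 0.0358 with library totals or 0.0437 without Ctrl 2). Predicted genes overlap Oxct1 and Bdh1. Translational efficiency values were −0.16 for Acat1, −0.01 for Oxct1 and 0.11 for Bdh1, with adjusted p from 0.606 to 0.983 and a sign of Oxct1 that depended on the setting. Of the list's 8 genes 1 rose (the transporter Slc16a1, 0.19) and 1 fell in RNA, 2 and 1 adjusted over the list alone (camera 0.642). In footprints 1 rose and 2 fell, 1 and 3 adjusted over the list alone, with a median of 0.03, a mean of 0.08 and a camera direction of down (0.776).

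Ribosome footprints in cKO hearts largely followed the RNA. Gdf15 footprints rose from 1.36 ± 0.0466 to 45.7 ± 1.43 CPM (5.06, SE 0.14), Nppa from 344 ± 36.1 to 4229 ± 763 and Acta1 from 434 ± 12.8 to 3074 ± 26.2 (SD, n = 2 each). Pfkfb1, an enzyme that sets the level of a glycolysis activator, fell from 15.7 ± 0.609 to 4.60 ± 0.717 CPM (−1.77, SE 0.15, adjusted p = 1.6e-06). Of 13514 genes tested, 1231 rose and 990 fell in edgeR's test, 336 and 69 of them at least 2-fold, and libraries of the genotypes were apart for 55.9% of genes against 33.3% by chance. With library totals the split was 1639 up and 657 down. Across the 12662 genes tested in both assays, log2 fold changes had a Spearman correlation of 0.553 and a Pearson correlation of 0.701, where genes are not independent replicates. Of these, 676 rose in both (99.8 for independent lists), 493 fell in both (65.6) and 0 went opposite ways, where independent lists would give 83.1 and 78.8. The labels do not say whether both assays used the same hearts. If so, differences between hearts would enter both lists, and independent lists would not be a fair baseline.

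**Figure D3:**
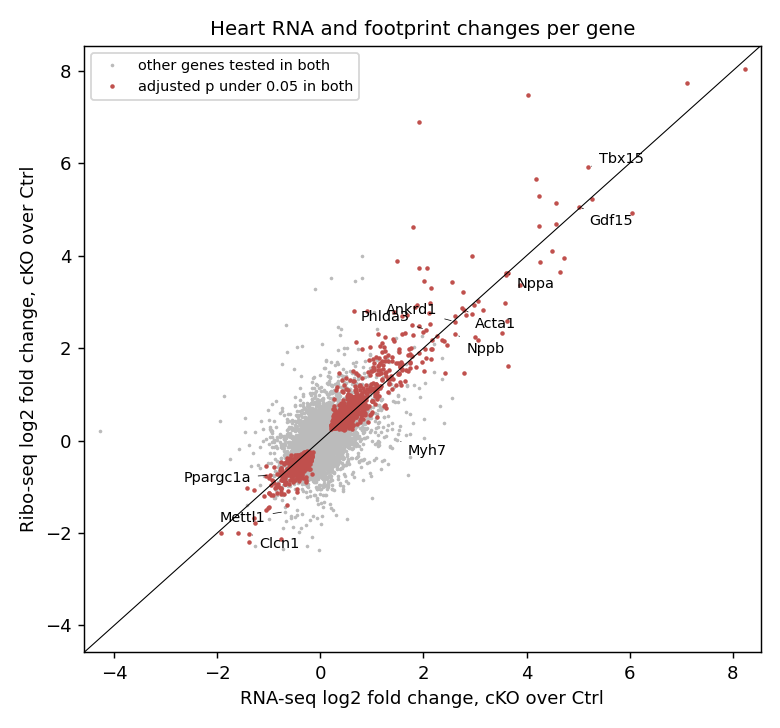
Log2 fold change, cKO over Ctrl, of RNA (x axis) and of footprints (y axis) for the 12662 genes tested in both assays (2 against 2 libraries each), with genes past adjusted p 0.05 in both in red and the line of equal change in black. Myh7 lies right of the line, with 1.49 in RNA and 0.00 in footprints.

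Tbx15 (5.92), Tnfsf18 (5.66), Gsta1 (5.14), Aqp8 (4.69), the innate immune regulator gene Nlrc3 (3.89) and the tubulin gene Tubb3 (3.74) also headed the rise in footprints. Tchhl1 had 3 footprints in Ctrl and 158 in cKO, a ratio of 42.1 (95% counting interval 14.1 to 206). Values of Tbx15 and Tnfsf18 moved by over 1.5 times on leaving out a Ctrl library, to 6.69 without Ctrl 1 and 5.28 without Ctrl 2 for Tbx15 and to 5.07 and 7.31 in Tnfsf18. Gsta1 reached 5.84 in such a fit. Beside Pfkfb1 (−1.77, overlapped by Apex2) and Mettl1 (−1.54), the genes named by rule that fell were Clcn1 (−2.02), Lrat (−1.997), Gfra4 (−1.68), the nuclear receptor gene Nr4a2 (−1.67), Col2a1 (−1.51) and Sema6c (−1.50). Of these, Lrat lost its call without Ctrl 1 (−1.18, adjusted p = 0.106), Gfra4 without Ctrl 2 (0.104), and Col2a1 in DESeq2 (0.294) and without Ctrl 2 (−0.31, 0.467). Nr4a2 stood at −1.10 without Ctrl 1, and Col2a1 at −2.12.

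In footprints 25 of 42 lists passed camera, 0 with an estimated correlation (9 at an unadjusted p under 0.05) and 11 by fry. Of 21 p53 targets 13 rose and 0 fell, 16 and 0 adjusted over the list alone (median 0.68, camera 6.4e-15, adjusted p = 0.188 with an estimated correlation), with Eda2r at 2.97 and Phlda3 at 2.40. Of 26 citric acid cycle genes 20 fell and 0 rose, 22 and 0 adjusted over the list alone (median −0.38, camera 2.2e-14, adjusted p = 0.188 with an estimated correlation), with Idh3a and Mdh1 at −0.59 each. Of 30 fatty acid oxidation genes 18 fell and 0 rose, 22 and 1 adjusted over the list alone (camera 1.1e-09, adjusted p = 0.188 with an estimated correlation), and of 19 amino acid catabolism genes 15 fell and 0 rose, 16 and 0 adjusted over the list alone (camera 1.2e-11, adjusted p = 0.249 with an estimated correlation). Of 30 integrated stress response genes 12 rose and 3 fell, as adjusted over the list alone (median 0.46, camera 2.3e-07, adjusted p = 0.188 with an estimated correlation). Among those that rose were Slc7a5 (1.73), Ddit3 (1.67) and Atf5 (1.30). Atf5 was read on a frame of 58 codons upstream of the longest, which has 217. Before scaling, Atf5 footprints went from 431 in Ctrl to 1396 in cKO on that frame and from 79 to 136 on the longest. Atf4 was also read on an upstream frame, of 59 codons where the longest has 288. Footprints on such frames do not measure translation of the longest one. Of 20 synthetases 9 rose and 1 fell, 11 and 2 adjusted over the list alone (camera 4.4e-05, adjusted p = 0.188 with an estimated correlation), with Lars at 0.73. Fetal genes (7 rose and 3 fell of 22, 8 and 3 adjusted over the list alone, camera 5.0e-15), heat shock genes (9 and 0 of 18, 9 and 0 adjusted over the list alone, 2.5e-08) and skeletal myogenic genes (8 and 2 of 19, 8 and 5 adjusted over the list alone, 7.2e-07) had an adjusted p = 0.188 with an estimated correlation. So did adult cardiomyocyte genes, where 2 rose and 12 fell of 32, 3 and 15 adjusted over the list alone (camera 5.1e-05). Atp2a2 of that list, at −0.75, was read on a frame of 38 codons upstream of the longest, which has 1044.

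Mitochondrial lists also passed in footprints. Of 59 mitochondrial ribosomal proteins 16 fell and 5 rose, 22 and 7 adjusted over the list alone, with Mrps22 at −0.62 and Mrps6 at 0.61 (camera 0.00797, adjusted p = 0.264 with an estimated correlation). Of 49 respiratory chain genes 12 fell and 1 rose, 12 and 2 adjusted over the list alone, with Ndufs1 at −0.67 (camera 0.00799, adjusted p = 0.273 with an estimated correlation), and their median of −0.06 became 0.01 with library totals. Of 15 mitochondrial chaperones 5 fell, 6 adjusted over the list alone, with Trap1 at −0.67 (camera 0.00460, adjusted p = 0.264 with an estimated correlation). Of 19 glycolysis genes 7 fell and 1 rose, the same adjusted over the list alone, with Ldha at −0.65 (camera 0.0179, 0.131 without cKO 2, adjusted p = 0.537 with an estimated correlation). Of 41 ribosomal proteins 16 rose and 1 (Rpl32, −0.78) fell, 19 and 3 adjusted over the list alone (camera 0.0196, 0.192 without cKO 1, adjusted p = 0.537 with an estimated correlation). The 10 other lists had camera values from 0.00155 (atrial markers) to 0.0306 (interferon response, where Ifit2 rose by 0.81), and adjusted p from 0.273 to 0.602 with an estimated correlation. Of these, 5 lost their call without Ctrl 1 and again without cKO 1: atrial markers (0.112 and 0.254), endothelial markers (0.0776 and 0.204), erythroid markers (0.13 and 0.254), matrix genes (0.437 and 0.188) and mitochondrially encoded genes (0.324 and 0.0568). ER chaperones lost it without Ctrl 1 (0.0600) or cKO 2 (0.0539), the interferon response without Ctrl 1 (0.0707) or cKO 2 (0.218) and skeletal muscle markers without Ctrl 2 (0.0885).

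Translational efficiency, the footprint to RNA ratio, differed for few genes in the main test, which had no block. Ivns1abp, an actin-binding protein gene, had a higher ratio in cKO by 1.06 (SE 0.11, adjusted p = 1.4e-04), Ucp2, a mitochondrial carrier gene, by 0.77 (SE 0.11, adjusted p = 0.00905) and Eef1a1, a translation elongation factor gene, by 1.08 (SE 0.14, adjusted p = 0.00223), each in edgeR's interaction test over 8 libraries. Myh7 had a lower ratio (−1.503, SE 0.26, adjusted p = 0.0306): its RNA rose while its footprints stood at 672 ± 286 and 674 ± 63.1 CPM. Of 12662 genes 16 passed, 9 higher and 7 lower, and 1227 had an unadjusted p under 0.05. With the RNA and footprint library of 1 genotype and number joined as a block, 134 passed, 48 higher and 86 lower. DESeq2 gave another balance, 10 higher and 36 lower, with 13 of the 16 among them. Eef1a1 lost its call without cKO 1 (adjusted p = 0.0662), Ucp2 without Ctrl 1 (0.1003), cKO 1 (0.380) or cKO 2 (0.0801), and Myh7 in DESeq2 (0.131) and without cKO 1 (0.498) or cKO 2 (0.235).

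Nlrc3 (2.37), Endou (2.14), Dab2ip (2.04), Ywhaz (0.92), Ost4 (0.83) and Tubb2a (0.67, outside the naming rule and chosen after its value was seen) were the others with higher ratios. Phb (−1.39), Polr2c (−0.996), Rpl32 (−0.96), Pdlim5 (−0.86), Hist1h1c (−0.66) and Tpm1 (−0.58) were the others with lower ratios, with adjusted p up to 0.0493 over all 16. Dab2ip was read on a frame of 32 codons where the longest has 1189, Ost4 on 33 of 48 and Pdlim5 on 239 of 482. The Ost4 frame of 48 codons had 0 footprints in each library. Before scaling, footprints on the kept Ost4 frame went from 543 in Ctrl to 1596 in cKO. Those on an Ost4 frame of 37 codons, downstream of the kept one, went from 243 to 293. On the longest frame the sign turned for Dab2ip (−0.44) and Pdlim5 (0.33). With footprints summed over all frames Ivns1abp stood at 0.51 (adjusted p = 0.145), Ucp2 at 0.17 (0.615), Ost4 at 0.53 (0.255) and Phb at −0.78. Ivns1abp footprints on its frame of 642 codons went from 7337 in Ctrl to 22595 in cKO, and those on a frame of 24 codons from 6649 to 7034, before scaling. Without Ctrl 1, Ctrl 2, cKO 1 and cKO 2 in turn, 7, 5, 2 and 7 of the 16 kept their call, and of the 15 named by rule Dab2ip and Ivns1abp kept it each time. Phb stood at −0.91 without cKO 1. In Ctrl, 8 of the 16 had ratios below the 10th percentile of all genes, and Eef1a1, Ywhaz, Tpm1, Phb, Rpl32, Tubb2a, Hist1h1c and Myh7 have close copies, so the split of their counts is uncertain. Genes also overlap Myh7 (Mhrt), Ost4 (Agbl5), Polr2c (Dok4) and Rpl32 (Cand2).

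**Figure D4:**
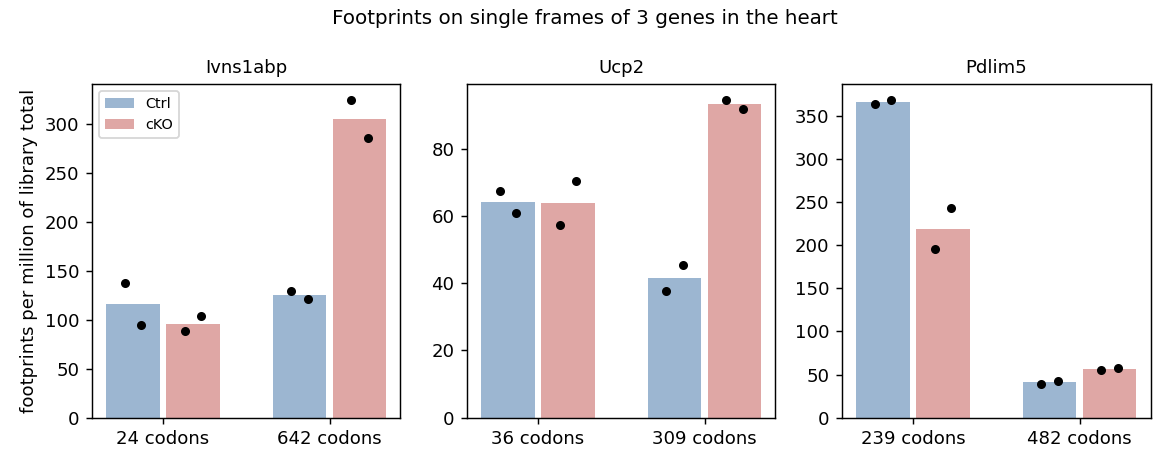
Footprints scaled to library total (y axis, in the unit of CPM without TMM factors) on pairs of frames of Ivns1abp, Ucp2 and Pdlim5 in the heart; points are libraries and bars are means of 2 per genotype. The frame of 642 codons of Ivns1abp is higher in both cKO libraries than in both Ctrl libraries, and the frame of 239 codons of Pdlim5 is lower in both.

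Ratios of mitochondrial lists were lower in cKO with 0 or 1 of their genes past the test. In the citric acid cycle list 0 of 26 genes passed in edgeR (7 at an unadjusted p under 0.05, 3 lower adjusted over the list alone), the median was −0.13 and camera gave 4.1e-04 (adjusted p = 0.365 with an estimated correlation). Sdhb had −0.43 (adjusted p = 0.119) and Mpc1 −0.55 (0.234). In the mitochondrial ribosomal protein list 0 of 59 passed (14 unadjusted, 5 lower adjusted over the list alone), with a median of −0.11 and camera at 0.00140 (adjusted p = 0.711 with an estimated correlation; 0.0508 without Ctrl 2 and 0.218 without cKO 1). In the respiratory chain list 0 of 49 passed (15 unadjusted, 0 adjusted over the list alone), with a median of −0.12 and camera at 0.00140 (adjusted p = 0.711 with an estimated correlation; 0.203 without Ctrl 2 and 0.4504 without cKO 1). The fatty acid oxidation list (0 of 30 genes, 5 unadjusted, 2 lower adjusted over the list alone) had a camera value of 0.0106, which was lost without Ctrl 1 (0.130), cKO 1 (0.0643) or cKO 2 (0.0735), and an adjusted p = 0.365 with an estimated correlation. Mitochondrial chaperones (Phb lower, 2 adjusted over the list alone; camera 0.0205, 0.0535 with summed frames, 0.14 without Ctrl 1, 0.105 without cKO 1 and 0.0730 without cKO 2) had an adjusted p = 0.365 with an estimated correlation, and ER chaperones (0 of 21, 3 unadjusted, 3 lower adjusted over the list alone; camera 0.0125, 0.127 without Ctrl 1 and 0.144 without cKO 1) had an adjusted p = 0.711 with an estimated correlation. Ratios of p53 targets were higher (0 of 20, 4 unadjusted, 2 adjusted over the list alone; median 0.26, camera 0.0275), with an adjusted p = 0.365 with an estimated correlation, and lost the camera call without Ctrl 1 (0.130), Ctrl 2 (0.0667) or cKO 2 (0.101). In all 7 of 39 lists passed, 0 with an estimated correlation (5 unadjusted) and 1 by fry.

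In Mettl1-null H9C2 cells, genes of cholesterol and fatty acid synthesis fell together. Insig1, a sterol-regulated brake on that pathway, fell from 328 ± 7.18 to 94.0 ± 1.01 CPM (SD, n = 3 each), the desaturase gene Scd from 282 ± 22.1 to 49.1 ± 1.81 (−2.52, SE 0.07) and Cyp51, a sterol demethylase gene, from 844 ± 25.3 to 308 ± 7.79. Of 30 genes in the list 26 fell and 0 rose, 27 and 1 adjusted over the list alone (median −0.90, camera 1.8e-78, adjusted p = 0.00960 with an estimated correlation). Of 19 p53 targets 13 rose and 2 fell, the same adjusted over the list alone (camera 2.6e-09, adjusted p = 0.0406 with an estimated correlation), with Cdkn1a from 185 ± 7.94 to 350 ± 14.7 CPM and Mdm2, which degrades p53, at 0.84. Of 14801 genes tested, 2014 rose and 1706 fell in edgeR's test, 584 and 128 of them at least 2-fold, and libraries were apart for 42.6% of genes against 10% by chance. The null samples are 1 edited line set against unedited cells, so differences between clones stand beside the loss of Mettl1. Whether the H9C2 counts are reads or were derived from transcript coverage is not given in the sources used here.

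Fbln1, a matrix protein gene, rose from 0.791 ± 0.139 to 32.0 ± 0.942 CPM (5.34, SE 0.13, adjusted p = 2.2e-07), and the extracellular superoxide dismutase gene Sod3 from 0.503 ± 0.226 to 13.8 ± 2.57. Aatk (5.32), Ces2c (5.08), Lgr6 (4.96), Sult5a1 (4.93) and Ptprf (4.50) rose as well, with Aatk at 6.41 without WT 3, Sult5a1 at up to 5.55 and Ptprf at up to 5.14 without 1 replicate. Mgat3 rose by 5.73 but had counts in WT 1 alone of the WT libraries: its value was 11.134 without WT 1, set by a group at 0 counts, and 5.143 without WT 3. The phospholipid transporter gene Abcb4 fell from 14.9 ± 1.42 to 0.525 ± 0.0607 CPM (−4.82, SE 0.14). Tmem144 (−5.83), Cenpb (−5.02), Aldh5a1 (−3.34), Rhox5 (−2.53) and Clic5 (−2.52) fell too. Without 1 replicate Cenpb reached −5.65 and Clic5 −3.15. The 10 counts of Tmem144 in the null samples were all in null 3, and without it the value was −10.581, set by a group at 0 counts.

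In H9C2 15 of 35 lists passed camera, 2 with an estimated correlation (10 unadjusted) and 25 by fry. Of 19 NRF2 genes 11 rose and 0 fell, 13 and 0 adjusted over the list alone (camera 9.2e-14, adjusted p = 0.167 with an estimated correlation), with Nqo1 from 131 ± 7.10 to 507 ± 9.70 CPM and Gsta1 at 4.40. Of 31 integrated stress response genes 14 fell and 2 rose, 18 and 4 adjusted over the list alone (median −0.23, camera down 2.7e-06, adjusted p = 0.167 with an estimated correlation): Asns, the asparagine synthetase gene, fell from 230 ± 4.42 to 113 ± 4.59 CPM and Psat1 of serine synthesis by 0.79, while Ddit3 rose by 0.57. The list's mean was 0.06, opposite in sign, through Fgf21, which had 0 counts in WT and 57 in the null samples, at least 18.5-fold higher against 3 counts over the group. With Fgf21 at that bound the mean was −0.04 and the median −0.23. Of 20 synthetases 11 fell and 0 rose, as adjusted over the list alone, with Gars at −0.67 (camera 6.1e-05, adjusted p = 0.139 with an estimated correlation). Of 74 ribosomal proteins 34 fell and 0 rose, 48 and 0 adjusted over the list alone (median −0.29, camera 1.5e-08, adjusted p = 0.562 with an estimated correlation, 0.0874 by fry). The list's mean log2 level was 8.319, 8.550 and 8.137 in WT 1 to 3, and its mean difference of −0.28 was −0.17 without WT 2 (camera 6.2e-06) and −0.38 without WT 3 (3.0e-18). Of 32 translation factors 12 fell and 0 rose, 15 and 0 adjusted over the list alone, with Eef2 at −0.35 (camera 0.00135, adjusted p = 0.167 with an estimated correlation).

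Of 35 matrix genes in H9C2 15 rose and 5 fell, 16 and 6 adjusted over the list alone, with Spp1 at 1.38 and Tgfb2 at 0.93 (camera 9.9e-07, adjusted p = 0.167 with an estimated correlation). Of 10 smooth muscle genes 7 rose and 1 fell, as adjusted over the list alone, with the kinase gene Mylk from 7.72 ± 0.635 to 65.7 ± 3.50 CPM (camera 7.4e-05, adjusted p = 0.167 with an estimated correlation). Of 12 fetal cardiomyocyte genes 8 rose and 0 fell, 9 and 0 adjusted over the list alone, with Ankrd1 at 0.59 and Acta1 at 2.31 (camera 5.2e-04, adjusted p = 0.167 with an estimated correlation). Of 25 interferon response genes 8 rose and 3 fell, 12 and 3 adjusted over the list alone, with Gbp2 at 1.42 (camera 0.0218, adjusted p = 0.167 with an estimated correlation). Of 19 amino acid catabolism genes 7 fell and 0 rose, 10 and 1 adjusted over the list alone, with Ppm1k at −1.07 (camera 0.00466, adjusted p = 0.167 with an estimated correlation). Citric acid cycle (7 fell of 25, Suclg2 at −0.64), mitochondrial ribosomal (10 fell and 1 rose of 55) and respiratory chain genes (7 fell and 1 rose of 47) had 7, 10 and 5 lower adjusted over the list alone and camera values of 0.0307, 0.0307 and 0.0314. These were lost with an estimated correlation (adjusted p = 0.562, 0.741 and 0.771) and without WT 2 or null 1. Ketone body genes did not pass (camera 0.3995), though Oxct1 fell from 300 ± 19.5 to 207 ± 1.14 CPM, and neither did skeletal myogenic genes (0.0660), where Tnnt2 fell by 1.57 and Myod1 rose by 0.71.

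Heart and H9C2 shared few changes beyond chance. Among 10417 genes of 1 symbol tested in both, 171 rose in both (124.7 for independent lists), 125 fell in both (92.6), 114 rose in the heart and fell in H9C2 (115.4) and 103 did the reverse (100.1). Log2 fold changes had a Spearman correlation of 0.033 and a Pearson correlation of 0.070 across genes (Spearman −0.017 without WT 3 and 0.089 without WT 2), which are not independent replicates. Acta1, Eda2r (2.12 in the heart, 2.28 in H9C2) and Spp1 (1.23, 1.38) rose in both, and Gpt2 (−0.76, −0.68), Bckdhb (−0.59, −0.69) and Ppm1k (−0.54, −1.07) of amino acid breakdown fell in both. Insig1 (0.75, −1.80), Scd2 (0.72, −2.22), Asns (0.77, −1.03) and Slc7a5 (1.20, −0.58) rose in the heart and fell in H9C2.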

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

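The results in this part were picked after the directions of the lists had been seen, and the differences between heart and H9C2 were not tested. A permutation of labels gives its smallest possible value to any list picked for full separation in opposite directions, so it carries no information here. Cytosolic aminoacyl-tRNA synthetases and cytosolic ribosomal proteins drew attention for their separation. Each list was higher in both cKO heart libraries than in both Ctrl libraries and lower in all 3 null samples than in all 3 WT samples. For the 20 synthetases the mean log2 level differed by 0.23 between cKO and Ctrl hearts and by −0.20 between null and WT cells, a difference of 0.430 between the contrasts. For ribosomal proteins (77 mouse and 74 rat genes) the differences were 0.25 and −0.28, or 0.529 between the contrasts. Both of these depend on single libraries: the heart difference ran from 0.141 without cKO 1 to 0.356 without cKO 2 and the H9C2 difference from −0.173 without WT 2 to −0.380 without WT 3, and the separation in H9C2 was thin (8.137 in WT 3 against 8.121 in null 2). Without any 1 library the synthetase differences stayed between 0.215 and 0.239 in the heart and between −0.198 and −0.211 in H9C2. These 2 were among 9 lists past camera in both heart RNA and H9C2, and the other 7 were not apart in opposite directions. Of the 7, the integrated stress response list also passed camera upward in the heart and downward in H9C2. Its differences were 0.368 and −0.065, or 0.432 between the contrasts, but its null and WT levels overlapped. Heart and H9C2 also differ in species, in tissue against cell line and in how Mettl1 was removed, so the difference cannot be tied to any 1 of these, and its cause was not tested.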

How the results depend on the processing

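The settings with footprints summed over frames or read on the longest frame, and correlations without 1 library, were chosen after the data were seen, and the others before. Calls of the named genes reported here in H9C2 were the most stable: 217 of 221 gene and setting pairs kept direction and side of the threshold, and 4, all of Wdr4, changed direction. In Ribo 249 of 259 did so, in heart RNA 200 of 215 and in translational efficiency 186 of 234, with 10, 9 and 43 no longer past the threshold, 0, 6 and 0 newly past it and 0, 0 and 5 of opposite sign.

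Counts of changed genes moved by over 1.5 times with a 2-fold threshold in each comparison, with DESeq2 in heart RNA and translational efficiency, with the block in translational efficiency, and without single replicates in each. Requiring a 2-fold change left 292 in heart RNA, 405 in Ribo, 7 in translational efficiency and 712 in H9C2. DESeq2 called 1080 genes in heart RNA, all among the 2032, and 46 in translational efficiency (10 higher, 36 lower, against 9 and 7), among which were 13 of the 16. Leaving out 1 replicate gave 1155 to 2002 genes in heart RNA, 1148 to 1940 in Ribo, 2 to 11 in translational efficiency and 2354 to 4455 in H9C2. Such fits have fewer samples, and in the heart they leave 1 library in a group, which is assumed to vary like the other group. Lists past the threshold without 1 replicate numbered 18 to 20 in heart RNA, 18 to 26 in Ribo, 3 to 6 in translational efficiency and 12 to 18 in H9C2. With an estimated correlation 0, 0, 0 and 2 lists passed, and fry, which asks another question, called 11 in Ribo, 1 in translational efficiency and 25 in H9C2. Summed frames gave 2243 genes in Ribo and 13 in translational efficiency. The longest frame gave 2228 (2171 shared with the 2221) and 14 (13 shared with the 16). With at least 50 counts the correlation of heart RNA and Ribo changes was 0.636, and that of heart and H9C2 was 0.026. Without 1 library they ranged from 0.480 to 0.527 and from −0.017 (without WT 3) to 0.089 (without WT 2).

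Values that changed sign were small, apart from those of Dab2ip and Pdlim5. In translational efficiency Oxct1 stood at 0.005 with factors per assay, 0.005 without Ctrl 1 and 0.063 without cKO 2 (range −0.054 to 0.063). On the longest frame Dab2ip stood at −0.436 and Pdlim5 at 0.332, since other footprints are then counted. Wdr4 in H9C2 stood at 0.020 with library totals and at 0.016, 0.026 and 0.013 without WT 1, WT 2 and null 1 (−0.102 to 0.026). For the other results that were not kept the cause was not tested.

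With the replicate number as a block across genotypes, heart RNA had 2745 changed genes, Ribo 2727 and H9C2 3147, and 21, 25 and 19 lists passed. Mettl1 RNA then had an adjusted p of 0.0499 and Acat1 RNA one of 0.0443. In translational efficiency the block joined the RNA and the footprint library of 1 genotype and number instead. It gave 134 genes (48 higher, 86 lower, against 9 and 7) and 8 lists. The labels give equal numbers across groups but no shared litter or day. Deviations of same-numbered libraries correlated at 0.009 in heart RNA, −0.040 in Ribo and 0.007, 0.048 and −0.053 in H9C2, and RNA with Ribo of 1 number at 0.166 in Ctrl and 0.090 in cKO. The main tests did not take the numbers as pairs, a choice fixed beforehand from the labels and not from these correlations. Those of RNA with Ribo were positive, so matching of the assays by number stays open. In H9C2 not every sample correlated best with its own number.

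Depth limits genes near the floor most: Gsta1, Tchhl1, Tnfsf18 and Mgat3 had few or no counts in controls, so their folds are known loosely. The planned tRNA alternatives and the codon content relation were not run.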

Other observations

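Predictions for the tests in this part were set before their results were seen. The margins required in the tests of Myh7 and of upstream frames were tightened afterwards, and the upstream test was fixed on the longest frame after an early look. As first set, both predictions went against their explanation. Matched by number, Ctrl ratios of Myh7 lay within the range of the other sarcomere genes, and as many genes lost as gained upstream occupancy. With the tightened margins both explanations stayed open. Ratios of Myh7 with no matching of libraries by number were added last.

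Immediate early genes split in cKO hearts. Of 22 in the list, Myc, a growth regulator (1.06), and Ccn1, a matrix signal (0.63), rose in RNA, and 5 fell, among them Nr4a2 (−1.29, SE 0.17), Nr4a3 (−0.83, SE 0.15), Fosb and Fosl2 (−0.61, SE 0.09). Adjusted over the list alone 2 rose and 6 fell, and camera gave an adjusted p of 0.0912. Among 28 genes of cholesterol and fatty acid synthesis, Scd2, Insig1 and Hsd17b7 (0.53) rose in cKO heart RNA and 0 fell, 3 and 0 adjusted over the list alone (camera 0.824; median −0.02, mean 0.02). In footprints, where fast skeletal muscle markers had 6 tested genes, Mylpf rose by 2.17 and Tnnt3 by 3.81, 2 adjusted over the list alone (camera 0.0179, 0.0885 without Ctrl 2, adjusted p = 0.392 with an estimated correlation). Of 45 tRNA modification enzymes 2 rose and 1 fell in heart RNA, 2 and 1 adjusted over the list alone (camera 0.955). Tmem144 rose by 1.33 in cKO heart RNA and fell by 5.83 in null H9C2 cells (−10.581 without null 3, set by a group at 0 counts), and the citric acid cycle paralog gene Ogdhl fell by 0.84 in the heart and rose by 0.89 in H9C2.

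Frames upstream of the longest frame were counted in 3023 genes (4178 frames). Their share of footprints was 4.08% ± 0.144 in Ctrl and 4.30% ± 0.083 in cKO (SD, n = 2 each). This share was taken out of footprints on these frames and on the longest frame of the same genes. By that share the genotypes did not overlap, at 4.183 and 3.980% in Ctrl and 4.240 and 4.358% in cKO. Out of all footprints the genotypes overlapped, at 0.905 and 0.852% in Ctrl and 0.900 and 0.946% in cKO. Of 2071 genes tested for footprints on upstream frames relative to the longest frame, 4 gained in cKO (Acta2, Cystm1, Yap1 and Hcfc1r1) and 4 lost (Ivns1abp, Ucp2, Pla2g16 and Ankrd1) at adjusted p under 0.05 in edgeR, with 240 at an unadjusted p under 0.05. Over the 2071 genes the median log2 change of upstream occupancy relative to the longest frame was 0.094. This occupancy was lower in Ivns1abp (−1.54, SE 0.24, adjusted p = 0.00585) and higher by 1.73 in Acta2 (SE 0.29, adjusted p = 0.00663). Cystm1 had 0 and 0 upstream footprints in Ctrl and 22 and 20 in cKO. The hypothesis that upstream frames gain footprints when Mettl1 is lost may hold or not: 4 of 8 is 50% (exact 95% interval 15.7 to 84.3%), which leaves a majority of gains or of losses open.

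The lower RNA of citric acid cycle and fatty acid oxidation lists in cKO hearts could come from fewer cardiomyocytes. That alone, with the other cell types in fixed proportion, would raise markers of all of them alike. Endothelial markers were lower instead, with a median of −0.13 whose upper 95% bootstrap bound was −0.088, while macrophage markers were higher at 0.13 (0.06 to 0.22), and these move apart by more than their spread. A general fall of cardiomyocyte transcripts cannot be told apart from a fall of the fuel lists: the citric acid cycle median minus that of cardiomyocyte markers was −0.090 (95% bootstrap interval −0.27 to 0.10), which includes 0 with 10 markers. Fewer cardiomyocytes together with a shift among other cell types, such a shift by itself, and the loss of Mettl1, which the design names, stay open. They were not separated. Bootstrap draws (2000) were over genes, which move together, so these intervals are narrower than the libraries warrant.

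The lower translational efficiency of Myh7 might reflect Myh6 footprints counted at Myh7, since Myh6 had 22300 CPM in Ctrl RNA against 87.1 of Myh7 and the genes are near-identical in long stretches. That would put the Ctrl ratio of Myh7 above those of other sarcomere genes. Its mean log2 ratio in Ctrl, 3.205, lay under the highest of 8 others (Myl3, 3.643) and above the other 7 (next Tnni3, 2.290), at the 99.5th percentile of all genes. The labels do not tie RNA and footprint libraries to 1 heart: matched by number the Ctrl ratios of Myh7 were 3.47 and 2.936, and matched the other way 3.817 and 2.592, the first above Myl3 (3.680). The margin to Myl3 (0.439) was less than the spread of Myh7 with no matching (SD 0.669), so shared footprints stay open beside lower translation of Myh7, which Mhrt and Gm31251 also overlap.

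Lower translational efficiency of mitochondrial lists in cKO hearts could follow from a low level or short frame of their genes. Among 10000 random lists matched on RNA level and frame length, 3 had a median at or below the −0.12 of the 134 genes. The random lists stood at −0.05 (central 95% −0.09 to −0.02) and all tested genes at −0.02. Level and frame length therefore go with part of the shift. The 3 mitochondrial lists were picked for their low ratios, and random lists ignore correlation between genes. Their rank cannot decide whether level and frame length leave a remainder. The choice of 1 frame per gene was tested with summed frames, where 3 of 3 lists passed in the same direction, though that setting moves few genes. Open are the part of level and frame length and the correlation within the lists. Camera with an estimated correlation ended each call. It also ended the call of lists whose estimate was under the preset 0.01, such as fatty acid oxidation (−0.001). Those losses therefore need not come from correlation. Also open are the dependence of 2 of the lists on single libraries and lower translation of these mRNAs without Mettl1. For the last, codon content was not tested.

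The 3720 changed genes in H9C2 were set against other splits of the 6 libraries into 3 and 3. Of the 10 splits, 1 (the real one) gave as many, and the highest of the others gave 1 gene. With 10 splits no share under 0.05 can be reached.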
